A study of Mus musculus with 6 samples.

How the data were processed

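RNA was measured in 6 mouse myeloid cell lines, 3 with unaltered Srsf2 (WT) and 3 heterozygous for the P95H allele (P95H), each made from the bone marrow of its own mouse. The labels describe ribosome-depleted, stranded total RNA read as 150 bp pairs. They name sequencers of different models, and which was used was not settled. The groups and replicate numbers were taken from the sample titles. The replicate numbers were not treated as pairs, because the lines come from different mice.

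The labels list fastp 0.20.1, Salmon 0.14.1, DESeq2 and STAR 2.7.6a with the genome build mm10, without saying what each was used for. The deposited gene table and transcript table hold estimated counts. The deposited transcript table is identical to the estimated counts in the Salmon file of each library, which also gives TPM (length-normalised relative abundance) and effective transcript lengths. The authors do not say how gene values were made. In the deposited gene table, 99.68% of the values of at least 10 estimated counts lay within 1% of length-scaled TPM computed from the Salmon files, so its unit was taken as estimated counts scaled from TPM. The deposited junction tables hold counts of uniquely mapped and of multi-mapped reads crossing each splice junction. The deposited intron tables hold counts of reads in the same 19389 intervals in every library, and the tool that made them is not stated.

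The record lists each junction table under a sample of 1 genotype, while the name of the table carries the code of a sample of the other genotype. This holds for 6 of the 6 junction tables and for none of the other tables. The comparison of exons was made by the record, and the assignment by the code was tried beside it. Every exon value is therefore given for tables recorded under WT or under P95H. Each junction and intron table was also correlated, across genes with a mean of at least 20 reads, with the gene counts of each library after centring each gene.

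Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Gene positions and exons came from GENCODE M21 on GRCm 38, the assembly that mm10 names. Genes were tested with the edgeR quasi-likelihood test on rounded counts, with TMM normalisation and the default low-count filter. All tests were two-sided, and a result was called at a Benjamini-Hochberg adjusted p under 0.05. Of 55487 genes listed, 15527 were tested. Gene levels are given as counts scaled to a common library size (CPM) with SD over 3 lines. The biological coefficient of variation was 34.9%, and the median standard error of a log2 fold change was 0.18.

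There were 26 gene lists, of which 23 had at least 5 tested members. These were tested with limma camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2. The sex-linked list, the eosinophil list and the stroma and endothelium list had fewer members. Members past the threshold were counted over all genes and adjusted over the list alone.

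Transcript usage was tested with edgeR diffSpliceDGE (Simes) on 42635 transcripts of 9192 genes with at least 2 transcripts past the filter. Salmon point estimates carry an assignment uncertainty that this test does not see. Cassette exons were annotated internal exons with observed skipping. For each, the mean of the reads on its flanking junctions was set against the reads on the skipping junction in an edgeR quasi-likelihood model with a term for each library. The 6972 exons tested had at least 20 such reads in every library and a mean inclusion between 2 and 98%. An exon was called when its mean inclusion also differed by at least 10 points. The exon and usage models used the earlier form of the edgeR quasi-likelihood fit, and the gene and intron models the edgeR 4 form. Introns were tested as genes were, since the tables give counts only, and 10516 intervals passed the filter. The tetramers CCNG and GGNG were counted in the called exons, and the log2 ratio of the counts, each plus 1, was compared by a permutation test with 100000 resamples.

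The rule for named items, the gene lists, the tests and the alternatives not marked as added were fixed before the data were examined. Srsf2 comes first. Among called genes with a mean of at least 1 CPM and groups that do not overlap, the rule takes 12 per direction, and 0 genes met it. It adds up to 4 members of each list with the lowest p, of which the text prints 28, picked after the p-values of the members were seen. For exons and introns it takes 8 per direction, 1 per gene. It adds the event with the lowest p in each tested gene of the list of literature targets. For transcript usage it takes the 8 genes with the lowest adjusted p, of which the text prints 7. Items outside the rule are marked as chosen after their values were seen.

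The tests were run on simulated data with the means and spreads of these libraries. The gene test recovered 61 of 191 genes changed 2-fold and 137 of 196 changed 4-fold, and 12.9% and 12.2% of its calls were false. For exons the simulation used a single spread pooled over all exons, and the changed exons had mid-range inclusion. The exon test recovered 0 of 200 exons changed by 0.1 of inclusion and 38 of 200 changed by 0.2, with 0 false calls. The intron test recovered 178 of 184 introns changed 4-fold, and 3.26% of its calls were false. The usage test recovered 85 of 197 genes, but 67 of its calls (44.1%) were false, far above the 5% that the threshold aims at. With transcripts held to at least 5 estimated counts in every library, a filter added after this was seen, 26.5% were false.

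Alternatives covered normalisation, low-count filters, transcript length offsets, DESeq2, a replicate block, camera with an estimated correlation, limma fry, limma on logit inclusion, read minimums, multi-mapped reads, the assignment of the junction tables and the omission of each line. Added after the data were seen were the usage filter above, intron reads relative to host gene reads, the other form of the edgeR quasi-likelihood fit for genes, usage and exons, non-robust fits for usage and exons, and a near-Poisson dispersion and limma weighted by reads for exons. Reads on a sequence named IS, which the labels do not mention, were left out of the tests.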

Results

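The data describe Hoxb8-immortalised myeloid cells, which are bone marrow progenitors held in an immature, GM-CSF-dependent state by a retroviral Hoxb8. The cells carry a tamoxifen-activated Cre recombinase. RNA was taken 7 days after tamoxifen from 3 WT lines and 3 P95H lines. P95H is a substitution in the splicing factor SRSF2 that recurs in myeloid neoplasms. The gene table held 50380205, 59283056 and 45916329 estimated reads in the WT lines and 50049372, 50616984 and 41548387 in the P95H lines. Uniquely mapped junction reads numbered 32489747 to 52884029 per table. The intron tables held 8557042 to 11667573 reads, of which 81.7 to 84.3% lay in 168 intervals. Comparing the genotypes asks what the mutant allele changes in gene levels, transcript choice, exon inclusion and intron reads.

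Srsf2 itself (ENSMUSG00000034120.18, chromosome 11, 116849901 to 116853094) was measured at 372 ± 42.0 CPM in WT and 355 ± 34.7 CPM in P95H (SD, n = 3). The WT lines had 420, 355 and 342 CPM and the P95H lines 378, 371 and 315 CPM. Its log2 fold change was -0.07 with a standard error of 0.12, and the edgeR adjusted p was 0.971. The sign turned without WT line 1 (0.027) and without P95H line 3 (0.0098). These totals do not separate the mutant from the normal allele. Hoxb8, chosen after its values were seen, had a log2 fold change of -0.21 and Ezh2, a histone methyltransferase chosen in the same way, of -0.09, with edgeR adjusted p values of 0.955 and 0.953. Leaving out 1 line moved the value of Hoxb8 between -0.029 (without WT line 1) and -0.44 (without P95H line 3), and that of Ezh2 between -0.042 (without P95H line 1) and -0.15 (without WT line 3).

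No gene passed the edgeR test between the genotypes. Of 15527 genes tested, 0 were higher and 0 lower in P95H, 902 had an unadjusted p under 0.05, and the smallest adjusted p was 0.210. DESeq2 called 62 genes higher and 61 lower of 16750. Genes whose groups did not overlap numbered 1836 (11.8%), where chance gives 10%. Without P95H line 3, edgeR called 9 genes higher and 7 lower, without WT line 1 it called 1 lower, and without WT line 3 or P95H line 2 it called 1 higher.

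The genes with low p-values described here were chosen after their values were seen, and none was called in that edgeR test. Mgmt, a DNA repair enzyme for alkylated guanine, was measured at 0.106 ± 0.0595 CPM in WT and 3.62 ± 1.28 CPM in P95H (SD, n = 3). Hook1, a microtubule adaptor, had 0.0109 ± 0.0188 CPM in WT and 5.72 ± 4.90 CPM in P95H. Plekha5 had 0.0465 ± 0.0354 and 7.19 ± 5.24 CPM. In the other direction, the noncoding RNA Snhg11 had 34.8 ± 16.2 CPM in WT and 2.10 ± 0.985 CPM in P95H, and Enah, an actin regulator, had 23.1 ± 14.1 and 0.746 ± 0.0922 CPM. Cmtm3 had 23.6 ± 1.64 and 11.8 ± 0.886 CPM, a log2 fold change of -0.99 with a standard error of 0.11. Nup210, a nuclear pore protein, had 267 ± 11.3 and 184 ± 5.31 CPM, a log2 fold change of -0.54 with a standard error of 0.08. DESeq2 called each of these 7 genes. Under edgeR, Hook1 passed without P95H line 2 or P95H line 3 (adjusted p 0.0258 and 0.0180) and Enah without WT line 1 (0.0237).

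Among the fixed gene lists, camera called 4 between the genotypes, and 0 members of any list passed the edgeR test over all genes. Of 454 members tested, 36 had an unadjusted edgeR p under 0.05. DESeq2 called 5 members over all genes, namely Mycn, mt-Nd3, P4ha1, Pdk1 and Mgl2. Genes encoded by mitochondrial DNA had a median log2 fold change of -0.39 in P95H over 15 tested members and a camera adjusted p of 2.51e-06. This call was lost with an estimated correlation (adjusted p = 0.9896) and with fry (adjusted p = 0.336). Before adjustment, camera with the estimated correlation gave p = 0.0505 and fry p = 0.0146, in each case the lowest among the lists tested. Their share of all estimated reads was 5.81, 5.46 and 5.09% in the WT lines and 4.49, 4.16 and 5.49% in the P95H lines, so P95H line 3 lay above WT lines 2 and 3. The ribosomal RNA locus on chromosome 17 took 45.4, 45.8 and 49.4% of intron table reads in the WT lines and 52.8, 49.5 and 51.4% in the P95H lines. The totals include reads on the sequence named IS, which took 12.7, 19.1 and 11.7% in WT and 5.76, 7.73 and 11.9% in P95H. The narrow separation of these shares may therefore come from the totals and is not read as a difference in ribosomal RNA. Ribosomal RNA genes, the mitochondrial ones included, took 3.14, 1.93 and 2.28% of the gene table in the WT lines and 2.10, 1.86 and 2.96% in the P95H lines, which do overlap. Adjusted over the list alone, 3 members fell: mt-Nd3 by 0.91 and mt-Nd6 by 0.51, which encode subunits of respiratory complex I, and mt-Cytb by 0.40, of complex III, on the log2 scale. The next member, mt-Atp8, had a log2 fold change of -0.42 and an edgeR p of 0.0554 adjusted over the list alone. The median of the list without WT line 2 was -0.23. Glycolysis and hypoxia genes had a median of -0.11 over 24 gene identifiers and a camera adjusted p of 0.0268, lost with an estimated correlation (adjusted p = 0.9896). Adjusted over the list alone, 2 of them fell: P4ha1, a collagen prolyl hydroxylase, from 109 to 77.1 CPM, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, from 161 to 120.02 CPM. Genes of secondary granules and late neutrophils had a median of 0.32 over 25 members and a camera adjusted p of 0.0268, lost with an estimated correlation (adjusted p = 0.9896), with 0 members passing over the list alone. Camp, the cathelicidin, had 13.4, 0.310 and 33.7 CPM in the WT lines and 43.3, 80.3 and 7.47 CPM in the P95H lines. Without WT line 2 the direction of this list turned and the camera adjusted p was 0.840. Replication-dependent histone genes had a median of 0.16 over 21 members and a camera adjusted p of 0.0219, lost with an estimated correlation (adjusted p = 0.9896), with 0 members passing over the list alone. H2ac4, H3c3 and H2bc3 had log2 fold changes of 0.28, 0.31 and 0.46, and of 0.17 and 0.20 for H2ac4 and H3c3 without P95H line 2 and 0.30 for H2bc3 without WT line 2. Leaving out 1 line also ended calls by camera: of the list secondary granule and late neutrophil without WT line 1 (adjusted p 0.190) or P95H line 2 (0.167), of the list glycolysis and hypoxia without WT line 1 (0.208), WT line 3 (0.0861), P95H line 1 (0.302) or P95H line 2 (0.0696), and of the list replication-dependent histones without WT line 2 (0.0830), WT line 3 (0.155) or P95H line 2 (0.458). For the other 3 lists than the mitochondrial, fry gave an adjusted p = 0.909.

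The other 19 lists were not called by camera, with adjusted p values from 0.0619 to 0.986, and 3 lists had too few members to test. The counts of members in this paragraph are by edgeR over all genes. DESeq2 called 1 member each of the primary granule list (Mgl2, adjusted p 0.0372) and of the stem and progenitor list (Mycn, adjusted p 5.54e-05). Of the unfolded protein and integrated stress response list, 0 of 24 members passed, and Ddit3, a stress-induced transcription factor, had 10.0 CPM in WT and 6.51 CPM in P95H. Of the SR protein family, 0 of 23 passed. Its kinases Srpk2, Clk1 and Clk3 had log2 fold changes of -0.40, -0.30 and -0.40, and Clk4 of 0.27. The value of Clk3 was -0.23 without WT line 2. Of the primary granule and early neutrophil list, 0 of 20 passed, and Elane, the neutrophil elastase, had 3208 CPM in WT and 4108 CPM in P95H. Mgl2, a C-type lectin, had 7.06 and 39.4 CPM, and Cst7, a cysteine protease inhibitor, 124 and 150.2 CPM. Of the stem and progenitor regulators, 0 of 20 passed, and Mycn had 0.787, 22.1 and 3.12 CPM in the WT lines and at most 0.0718 CPM in the P95H lines. Of the cell cycle list, 0 of 32 passed, and Cdt1, a licensing factor for DNA replication, had 60.3 and 73.6 CPM. Among inflammatory genes 0 of 20 passed, and Nfkbie, Ptgs2 and Ccl3 had log2 fold changes of 0.48, -1.61 and -1.24, with -0.82 for Ptgs2 without WT line 2. Of the interferon response list, 0 of 20 passed, and Ifit2 had a log2 fold change of 0.70, and of 0.39 without P95H line 1. In the stroma and endothelium list, Pecam1, an adhesion molecule also found on blood cells, had 118 and 38.7 CPM, and 0 of 4 members passed.

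The transcript usage test called the genes named here, with the rate of false calls given below. In Hnrnpa2b1, an RNA-binding protein, the transcript ENSMUST00000090002.9 took 4.18 ± 0.846% of the gene's estimated counts in WT and 0.776 ± 0.206% in P95H (SD, n = 3). In Hnrnpa1, ENSMUST00000036004.15 took 1.11% in WT and was listed at 0 in P95H. Transcripts of Arcn1 (2.38%), Mark2 (6.82%) and Copg2 (3.31%) were likewise present in WT and listed at 0 in P95H. Those of Ccnt2 (8.01 ± 3.80%) and Plcb2 (9.96 ± 1.77%) were present in P95H and listed at 0 in WT. Over the genes listed at 0, a count of 0 allows a share of up to 0.00985% (Hnrnpa1) to 0.144% (Copg2) in a library, for counting error only and not for the uncertainty of assigning reads to transcripts.

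The edgeR diffSpliceDGE test called 98 of 9192 genes, the gene-level adjusted p running from 4.17e-12 for Arcn1 to 8.19e-09 for Copg2 among those named. This count is not a count of true changes, since 44.1% of the calls of this test were false in simulated data and another split of the 6 lines gave 119 where the genotypes gave 98. Leaving out 1 line gave 129 to 217 genes (180 without WT line 1, 177 without WT line 3 and 217 without P95H line 3), and the edgeR 4 fit, chosen after the data were seen, gave 373. With at least 5 estimated counts in every library, a filter chosen after the data were seen, 87 genes were called, 26 of them shared with the 98. Of the genes named above only Hnrnpa2b1 is among the 87, and the filter removes transcripts listed at 0 in a group by its construction. With that filter 26.5% of the calls were false in simulated data, and the highest count in another split was 50. Among these 87, chosen after their values were seen, were Tardbp, an RNA-binding protein, in which ENSMUST00000095719.9 took 1.29 ± 0.642% in WT and 6.19 ± 2.11% in P95H, and Plekhm2, in which ENSMUST00000030751.4 took 16.8 ± 2.72% and 52.7 ± 7.94%.

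The junction tables come with a conflict over which genotype they belong to. Each of the 6 tables is recorded under a line of 1 genotype and carries in its name the code of a line of the other. Across genes, 6 of the 6 junction tables correlated best with the gene counts of the library of their code (Pearson r 0.909 to 0.943), and 0 with those of the library they are recorded under. Of the intron tables, 6 of 6 correlated best with the library they are recorded under (r 0.572 to 0.691). With the library it is recorded under, each junction table had an r between -0.338 and 0.377, which argues against the record for these tables. These correlations are across genes, which are not independent replicates.

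**Figure D1:**
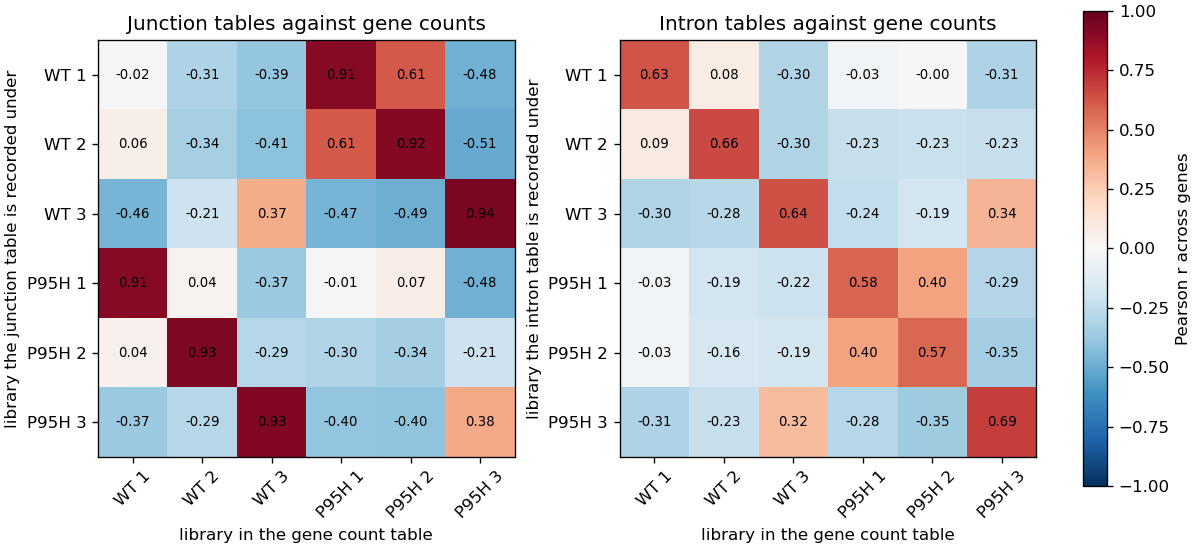
Pearson r across genes between each junction table (left) or intron table (right), by the library it is recorded under, and the gene counts of each library. Junction tables reach r of 0.909 to 0.943 with a library of the other genotype, and intron tables reach r of 0.572 to 0.691 with their own.

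Exons of named genes differed strongly between the sets of junction tables, and each direction below is by the record. By the code in the table names, which the gene counts match in every table, each direction is the opposite. That match and the signs by transcript TPM given below both argue against the record. By the code, an exon given here as more included under P95H is less included in P95H, and the reverse. In Hnrnpa2b1, an RNA-binding protein, the exon on chromosome 6 from 51464428 to 51464547 was included in 30.2 ± 0.933% of reads in tables recorded under WT and 64.4 ± 2.69% in tables recorded under P95H (SD, n = 3; edgeR adjusted p 1.08e-11). In Arhgef11, the exon on chromosome 3 from 87734424 to 87734552 was included in 22.0 ± 2.705% and 60.9 ± 7.94% (edgeR adjusted p 0.00114). Exons of Tctex1d2, Kctd17, Rnf111, Baz2b, Dap3 and Tmem80 were also more included in tables recorded under P95H, by 26.4 to 30.9 points. In Ppig, a cyclophilin, the exon on chromosome 2 from 69731491 to 69731580 was included in 51.8 ± 1.64% in tables recorded under WT and 20.4 ± 5.12% in those recorded under P95H (edgeR adjusted p 8.89e-06). In Gas5, a noncoding host of small nucleolar RNAs, the exon on chromosome 1 from 161037124 to 161037164 was included in 78.7 ± 0.756% and 57.4 ± 1.73% (edgeR adjusted p 7.57e-08). Exons of Cars2, Trmt13, Macf1, Rer1, Abi1 and Trmt2b were also less included in tables recorded under P95H, by -28.2 to -21.9 points.

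By the record, edgeR called 86 exons more included and 62 more skipped in tables recorded under P95H, of 6972 tested. They lie in 132 genes, and overlapping versions of an exon, such as those of Abi1 and Lat2, are counted apart. Without the table recorded under WT line 1, the counts of more included and more skipped exons were 50 and 32. They were 47 and 23 without that of WT line 2 and 58 and 38 without that of P95H line 2. By their codes these left-out tables belong to P95H line 1, P95H line 2 and WT line 2. With multi-mapped reads the counts were 65 and 40. Of all exons tested, called or not, 22.5% had groups that did not overlap, where chance gives 10%. By the code, 62 were more included and 86 more skipped in P95H. The call of Tmem80 was lost with multi-mapped reads, with the replicate block and in each fit without 1 junction table. That of Trmt13 was lost without the table recorded under WT line 1, WT line 2 or P95H line 1 (edgeR adjusted p 0.104, 0.0522 and 0.0556). That of Trmt2b was lost without the table recorded under WT line 1 or P95H line 2 (edgeR adjusted p 0.0873 and 0.0537). limma on logit inclusion called 0 exons with a difference of at least 10 points, with 1062 at an unadjusted p under 0.05, and its smallest adjusted p of 0.0330 belonged to a smaller difference.

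**Figure D2:**
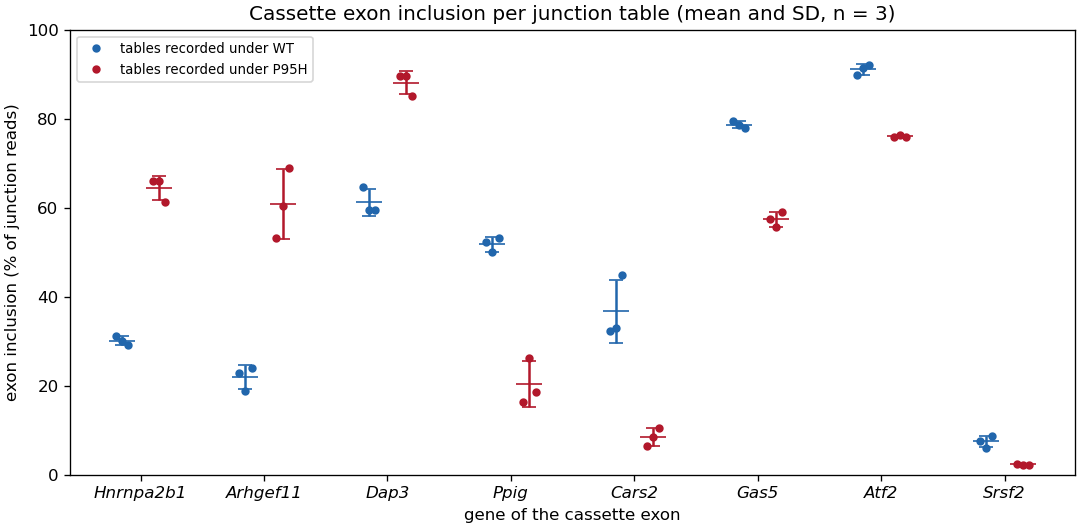
Inclusion of 8 cassette exons as a percentage of junction reads, per junction table (points) with the mean and SD of 3 tables, by the genotype each table is recorded under. The Hnrnpa2b1 exon averages 30.2% in tables recorded under WT and 64.4% in tables recorded under P95H. By the code in the table names, which the gene counts match, these are exchanged.

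The inclusion of the same exons was also computed from transcript TPM, whose library labels carry no such conflict. Inclusion in P95H minus WT was -30.5 points for Hnrnpa2b1, -32.4 points for Tctex1d2 and -15.4 points for Dap3. It was 18.6 points for Ppig, 24.7 points for Rer1 and 17.3 points for Gas5. Across 127 called exons with both values, the change by transcript TPM and the change by junction reads as recorded had a Pearson r of -0.873 (permutation p 1e-05, the smallest that 100000 resamples can give). The exons form 2 clusters, those more included and those more skipped, so the sign is the plainer measure. Overlapping versions of an exon, such as those of Abi1 and Lat2, entered both measures as if independent. The signs were the same in 5 exons by the record and in 122 by the code.

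**Figure D3:**
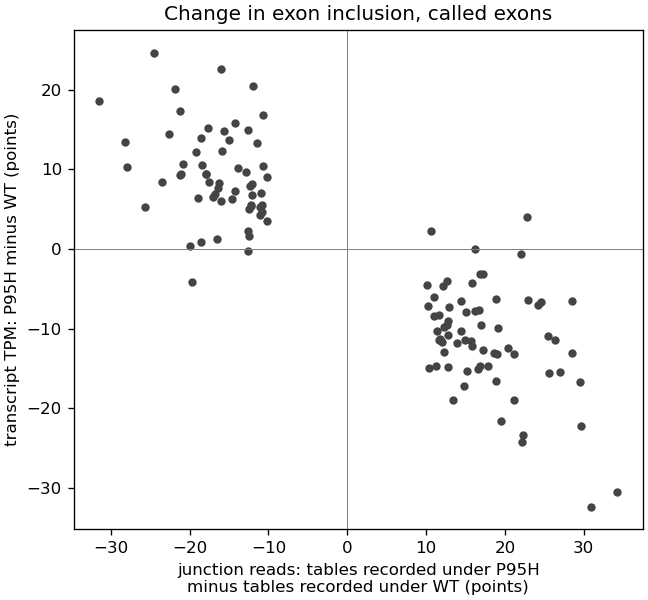
Change in inclusion of called exons in percentage points, from junction reads as recorded (horizontal) and from transcript TPM (vertical), 1 point per exon. The 127 points form 2 clusters in opposite quadrants, since called exons differ by at least 10 points, and 122 have opposite signs on the axes.

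Of the literature targets of mutant SRSF2, 18 genes had a tested exon and 5 passed the edgeR threshold. Directions are again by the record, and by the code each is the opposite. In each gene the tested exon with the lowest p was taken, which need not be the exon reported in the literature. That choice was not corrected for. Over all tested exons, 354 of 6972 passed the same threshold. Besides Hnrnpa2b1, an exon of Srsf2 was included in 7.47 ± 1.32% in tables recorded under WT and 2.30 ± 0.145% in tables recorded under P95H. An exon of Hnrnpm was included in 92.1 ± 0.0823% and 96.7 ± 0.613%, of Atf2, a transcription factor, in 91.1 ± 1.18% and 76.2 ± 0.287%, and of Gnas, a G protein subunit, in 85.6 ± 0.645% and 74.1 ± 1.80% (SD, n = 3). The exons of Hnrnpa2b1, Atf2 and Gnas also met the minimum difference of 10 points, and those of Srsf2 and Hnrnpm did not. By transcript TPM, inclusion in P95H minus WT was 13.6 points for Atf2 and 13.4 points for Gnas. The exon of Ezh2 annotated in a decay transcript was included in 4.04 ± 0.510% and 2.91 ± 1.05% (edgeR adjusted p 0.511). Exons of Tmem14c, Clk3, Atr, Slc25a26, Bcor, Map3k7, Hnrnph1, Pkm, Csf3r, Nasp, Cdc25c and Endov did not pass, with differences of -6.41 to 6.32 points.

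The called exons differed in the tetramers that SRSF2 binds. Exons more included in tables recorded under P95H held 1.53 CCNG and 3.58 GGNG per 100 nt. Exons more skipped in those tables held 2.93 CCNG and 1.06 GGNG per 100 nt, and the other 6824 tested exons 2.05 and 1.73. The mean log2 ratio of CCNG to GGNG was -0.96 ± 0.96 in the 86 exons and 1.09 ± 0.90 in the 62 (SD over exons), a difference of -2.05 (permutation p 1e-05, the smallest possible). By the code the difference is 2.05. The permutation treated overlapping versions of an exon, such as those of Abi1 and Lat2, as independent. In the Hnrnpa2b1 exon there were 3 CCNG and 14 GGNG, and in the Cars2 exon 6 CCNG and 1 GGNG. Other called exons named above did not follow this difference: Gnas, more skipped in tables recorded under P95H, held 1 CCNG and 3 GGNG, Dap3 2 and 2, Trmt2b 1 and 1, and Gas5 0 and 0.

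Intron reads changed at 2 places. The interval in Mgl2 on chromosome 11 from 70136777 to 70136920 had 9, 14 and 21 reads in the WT lines and 108, 86 and 162 in the P95H lines, a log2 fold change of 3.15 with a standard error of 0.36 (edgeR adjusted p 0.0143). The interval in Snhg11 on chromosome 2 from 158381041 to 158382503 had 55, 92 and 31 reads in WT and 2, 3 and 1 in P95H, a log2 fold change of -4.63 with a standard error of 0.45 (edgeR adjusted p 0.00219). The host genes had log2 fold changes of 2.49 for Mgl2 and -4.05 for Snhg11. Of 10516 intervals tested, edgeR called 1 higher and 1 lower in P95H, and 627 had an unadjusted p under 0.05. Relative to host gene reads, an alternative chosen after the data were seen, 0 of 9302 intervals were called by edgeR, with adjusted p values of 0.730 for Mgl2 and 0.848 for Snhg11, and 696 had an unadjusted p under 0.05. Without P95H line 1, 0 intervals were called, and without WT line 1 or WT line 2 the Mgl2 interval was not.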

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

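The comparison of each junction table with the gene counts and the count of exons in other splits of the 6 lines were chosen after the result was seen. Reads on a sequence named IS, which the labels do not mention and no comparison uses, made up 2.43, 3.28 and 4.50% of the uniquely mapped junction reads in tables recorded under WT and 5.37, 5.88 and 4.20% in tables recorded under P95H. In the intron tables they made up 12.7, 19.1 and 11.7% of the reads in the WT lines and 5.76, 7.73 and 11.9% in the P95H lines. By the code the junction shares change genotype, and WT line 2 then had the highest share and P95H line 1 the lowest in both kinds of table. In both kinds of table the groups overlap. These reads stand out because they are signal in data outside the main measurement, and their origin was not tested.

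The junction tables carry the codes of lines of the other genotype. Against the record as it stands, 0 of 6 tables were matched best by the gene counts of the library they are recorded under. An exchange of all the gene, transcript and intron tables instead would need exons more included in tables recorded under P95H to be richer in CCNG, if the mutant protein favours CCNG as is known for it, and the difference in log2 ratio was -2.047. Given that preference, this value argues against such an exchange. Between exon changes from junction reads as recorded and from transcript TPM, the r was -0.873. This r argues against the record and goes with junction tables listed under the other genotype. No biological explanation was tested for this pattern.

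The 148 exons called between the sets of junction tables include those of Hnrnpa2b1, Arhgef11, Ppig and Gas5. Unequal junction depth is argued against as the whole cause, since 117 exons were called when every exon was thinned to the reads of its shallowest library, and 105 of these were among the 148. With 10 splits of 3 lines against 3 no share under 0.05 can be reached: 1 of the 10 splits, the real split, gave as many exons, with 148, and the highest other gave 1. An effect of the allele may account for the calls and remains a hypothesis. The direction by the code had the sign of transcript TPM in 122 of 127 exons, the direction by the record in 5.

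The mitochondrially encoded genes had a median log2 fold change of -0.39 in P95H. A single line as the cause is argued against by the fits that leave out each line in turn, in which the highest camera adjusted p was 0.000471, at the preset correlation of 0.01, and the median nearest 0 was -0.23 (without WT line 2). The median was -0.391 with plain summed counts and length offsets. Those offsets correct for the same lengths as the deposited gene counts do, so this fit cannot test length scaling as a cause. The call was lost with an estimated correlation between genes (camera p 0.0505 before adjustment, adjusted p 0.9896). Co-varying members, such as a shared difference in RNA recovery, therefore stay open beside an effect of the allele. The share of intron table reads at the ribosomal RNA locus of chromosome 17 was 45.4 to 49.4% in WT and 49.5 to 52.8% in P95H. These shares are of totals that include the unevenly present reads on the sequence named IS, so their narrow separation cannot speak for uneven RNA depletion. Whether uneven RNA depletion goes with the fall was not tested.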

How the results depend on the processing

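The usage filter, intron reads relative to the host gene, the other forms of the edgeR fit for genes, usage and exons, near-Poisson dispersion and limma weighted by reads were chosen after the results were seen. Where no reason is given, the cause was not tested. For genes the edgeR count stayed at 0 and 0 with DESeq2 size factors, no low-count filter, a mean of at least 1 CPM, length offsets and the earlier edgeR fit. It was 2 higher with the replicate block (Rai14 and Plekha5, adjusted p 0.0168 each, Rai14 chosen after its values were seen), and DESeq2 called 62 higher and 61 lower. Leaving out 1 line gave 0 to 9 higher and 0 to 7 lower. The log2 fold change of Srsf2 ranged from -0.127 to 0.0269 without 1 line, above 0 without WT line 1 and without P95H line 3. Gene lists called fell to 0 with an estimated correlation and 0 with fry, and ran from 2 (without WT line 2 or P95H line 2) to 9 (without P95H line 3). With the replicate block 5 were called, the unfolded protein and integrated stress response list being added (adjusted p 0.0358). The adjusted p of the list secondary granule and late neutrophil ran from 1.12e-07 to 0.840, its direction turning without WT line 2. Genes with changed usage numbered 159 with a mean of at least 10 estimated counts, 152 with the F test, 373 with the edgeR 4 fit and 373 with its non-robust form, 98 with the non-robust fit, 82 with the replicate block, 87 with the usage filter and 129 to 217 without 1 line (180 without WT line 1, 177 without WT line 3, 217 without P95H line 3). In simulated data 41.1% of the calls of the edgeR 4 fit were false. Exons more included and more skipped in tables recorded under P95H numbered 24 and 12 with a difference of at least 0.2 and 222 and 132 with no minimum, which follows from the limit itself. They numbered 65 and 40 with multi-mapped reads, 0 and 0 with limma on logit inclusion, 139 and 106 with limma weighted by reads, 124 and 90 with near-Poisson dispersion, 97 and 72 with the edgeR 4 fit, 93 and 71 with its non-robust form, and 77 and 53 with the non-robust fit. Leaving out 1 junction table gave 47 to 71 and 23 to 49. By the line the table is recorded under, these were 50 and 32 (WT line 1), 47 and 23 (WT line 2) and 58 and 38 (P95H line 2). limma on logit inclusion lost the calls of 20 named exons, and the exon of Tmem14c passed with at least 50 reads, the edgeR 4 fit, near-Poisson dispersion and limma weighted by reads. DESeq2 called 12 named genes that edgeR did not. Introns higher and lower numbered 0 and 0 relative to host gene reads, 1 and 2 with the replicate block, and 0 to 1 and 0 to 3 without 1 line (3 lower without WT line 3, 0 and 0 without P95H line 1). The replicate numbers were not taken as pairs, since the lines come from different mice. Correlations of gene residuals within a number were 0.24, -0.08 and 0.32, and the highest with another number were 0.35, 0.06 and -0.23. For numbers 1 and 2 the value within the number was the lower. For number 3 it was the higher, so WT line 3 and P95H line 3 resembled each other.

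With the junction tables assigned by the code in their names, every named exon reverses, which follows from the exchange. Inclusion in P95H minus WT is then -38.9 points for Arhgef11, -34.2 for Hnrnpa2b1, -30.9 for Tctex1d2, -29.7 for Kctd17, -28.5 for Rnf111, -28.5 for Baz2b, -27.0 for Dap3, -26.4 for Tmem80, 31.4 for Ppig, 28.2 for Cars2, 28.0 for Trmt13, 25.6 for Macf1, 24.6 for Rer1, 22.7 for Abi1, 21.9 for Trmt2b and 21.2 for Gas5. Among the literature targets it is 5.18 for Srsf2, -4.52 for Hnrnpm, 15.0 for Atf2, 11.5 for Gnas, -6.07 for Tmem14c, -6.32 for Clk3, -3.72 for Atr, -5.37 for Slc25a26, 6.41 for Bcor, 1.13 for Ezh2, 5.82 for Map3k7, 0.901 for Hnrnph1, 3.27 for Pkm, 1.62 for Csf3r, 0.277 for Nasp, -1.20 for Cdc25c and 0.969 for Endov. The motif difference becomes 2.05. By the record and without 1 junction table, values ran from -0.819 to 3.94 for Cdc25c, -4.21 to 0.253 for Csf3r, -2.78 to 1.22 for Endov, -0.753 to 0.0230 for Nasp and -6.62 to 0.431 for Pkm. With no change of sign they ran from -8.85 to -4.17 for Bcor, -1.72 to -0.725 for Ezh2, -8.50 to -3.56 for Map3k7 and -1.81 to -0.271 for Hnrnph1. Not run were motifs with flanking intron sequence, since no genome sequence was used, introns with no minimum difference, since the tables hold counts only, and introns by the code, which equals the record. At the depth of these libraries and a single pooled spread, 0 of 200 simulated exons of mid-range inclusion changed by 0.1 were recovered. Depth was not varied apart from spread. In the real data 354 exons passed with no minimum difference and 148 with it, so this recovery does not carry over to all exons.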

Other observations

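The tests in other splits of the 6 lines for genes, usage (with each of its settings) and introns, and the test of chromosome medians, were chosen after the results were seen. Some genes of secondary granules and late neutrophils spread widely among lines of 1 genotype. Ltf, lactoferrin, had 1.49, 0.0326 and 13.5 CPM in the WT lines and 9.38, 38.03 and 3.49 CPM in the P95H lines, and Fcnb, a ficolin, had 18.1, 1.94 and 54.3 CPM and 60.4, 72.8 and 22.3 CPM. Mmp9, a gelatinase, was at 0.0163 to 2.48 CPM. Of the eosinophil list, 0 of 2 tested members passed the edgeR test, and of the sex-linked list 0 of 3.

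Genes on chromosome Y were unevenly present. WT line 3 had 1633 estimated counts of Ddx3y, 1617 of Eif2s3y, 1968 of Kdm5d and 785 of Uty. P95H line 1 had 340, 327, 12.5 and 195, and P95H line 3 had 8.70, 2, 4053 and 1661. In WT line 1, WT line 2 and P95H line 2 each of these genes had at most 36.9 estimated counts. Xist had at most 16.6 estimated counts in any line. For chromosomes 1 to 19 and X, a gained or lost chromosome in a line was tested by the median deviation of its genes, and the largest was 0.048 on the log2 scale, below the 0.1 set as the bound. Chromosome Y and segments smaller than a chromosome were not tested.

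The 6 lines can be split into 3 against 3 in 10 ways, the real split included, too few for a share under 0.05. For genes the real split gave 0 and the highest other 39, and since no split can give fewer than 0, the number of splits with as many says nothing. For usage the real split gave 98 and the highest other 119, with 87 against 50 for at least 5 estimated counts in every library and 373 against 238 for the edgeR 4 fit. For introns it gave 2 against 10, and for gene lists 4 against 13. The split of WT line 1, P95H line 1 and P95H line 2 from the rest gave the 39 genes, the 119 genes with changed usage and the 10 introns, which points to a structure of the lines other than genotype.

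A pair of hypotheses about the called exons was tested. If exons annotated only in decay transcripts lowered their host gene, gene levels would go opposite to inclusion by the code, and this held in 5 of 13 genes, 38.5% (exact two-sided binomial p 0.581), below the 60% set as the bound. By the record, which the gene counts do not match, it would hold in 8 of 13, 61.5%, just above that bound. The exact two-sided binomial p is the same, since the counts are complements. Under neither assignment was the share told apart from an even split. Some of these exons, such as those of Kctd17 and Htra2, share an edge with a coding exon and take in its junction reads. By the record the Kctd17 decay exon was included in 66.2 and 95.9%, and its coding version in 66.3 and 95.9%. For such exons the test does not measure the decay transcript alone. If called exons tended to keep the reading frame, their lengths would be divisible by 3 more often than those of other coding exons. This was seen in 56 of 93 called coding exons (60.2%) against 47.9% of the others, which is the direction of that hypothesis. The odds ratio was 1.65 (two-sided Fisher's exact p 0.0208). The test counts overlapping versions of an exon, such as those of Abi1 and Lat2, as independent. Called exons had to differ by at least 10 points, and the others were not matched to them for inclusion, so the cause stays open.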
